A study of Mus musculus with 78 samples.

How the data were processed

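Liver RNA from 78 mice in 26 groups of 3 had been sequenced as poly(A)-selected libraries. The 6-month groups (UM-HET3 mice, both sexes) were controls and mice given acarbose at 1000 ppm, rapamycin at 42 ppm, Protandim at 1200 ppm, 17-alpha-estradiol at 14.4 ppm or 40% calorie restriction for 2 months. The 12-month groups of that stock were controls and mice given acarbose at 1000 ppm, rapamycin at 14 ppm or 40% calorie restriction for 8 months. The other groups were males: C57BL6/J mice of 14 months on 0.12% or 0.86% methionine, and growth hormone receptor knockout and Snell dwarf mice of 5 months with controls of their own stocks. The deposited table held raw gene counts, as integers assigned to genes per library. Per the submitters' processing notes, reads were converted with bcl2fastq 1.8.4, trimmed with Trimmomatic 0.32, aligned to GRCm38 (mm10) with STAR 2.5.2b and counted with featureCounts 1.5. The notes do not state the strand of counting. The table had 43629 genes, 42462 of them with a symbol and 14660 with 0 counts throughout, and 78 columns, each matched to 1 sample. Of 822 list members, 821 were matched by symbol. Libraries held 15521588 to 37778510 assigned counts.

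Counts were analysed in R 4.3.3 with edgeR 4.0.16. Libraries were split into 5 sets (6 months, 12 months, methionine restriction, receptor knockout and Snell dwarf), and both ages were fitted together for differences between ages. In each set genes were kept by filterByExpr on the groups, which left 14816 genes at 6 months, 13639 at 12 months, 13858, 12571 and 12528 in the 3 male sets and 15159 in the joint fit. Libraries were scaled by TMM and a robust quasi-likelihood model was fitted with 1 coefficient per group. The effect of an intervention at 6 and 12 months was the mean of its female and male differences from controls of that sex, and a difference between sexes or ages was the difference of those effects. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. SEs came from the quasi-likelihood F statistic.

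Before the data were examined, 42 gene lists of liver pathways and cell types, the comparisons and the rule for naming genes were fixed. Lists were tested against the other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2, with a preset correlation of 0.01 and with a correlation estimated from the data; the 435 tests were adjusted together, and counts of members are also given adjusted over the list alone. Lists of genes with at least a 2-fold sex difference in controls were taken from the age whose libraries were not in the comparison, and 22 tests in males were adjusted together. Named genes were up to 8 per direction with the largest fold change among those that passed, had a mean log2 CPM of at least 2 and lay on the same side of the same-sex control mean in every treated library, without predicted or clone names. Results of some genes that met this rule are not reported here. They were joined by up to 4 members per list with the smallest adjusted p, by Ghr, Igf1, Igfals and Socs2 in the dwarf models, and by up to 5 per direction for differences between sexes or ages, for 17-alpha-estradiol within a sex and for the sexes in controls. Correlations between interventions were computed across genes, with a leave-one-library-out SE, and shared genes were compared with the number that independent calls would give.

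Alternatives were RLE size factors, no filter on low counts, a replicate block, a fit of the compared groups alone, DESeq2 1.42.0, the estimated correlation, textbook sex-biased lists, and leaving out each library in turn. The 6-month fit without 2 libraries and the fit without 9 libraries with over 1000 counts over marker genes of kidney, skeletal muscle, adrenal gland or pancreas were added after seeing the data. The bound was set after a first fit without 7 of the 9. A count was taken as moved beyond a ratio of 1.5. Counts were also made for other splits of the same libraries, 40 drawn with a fixed seed or all 10 for 3 against 3, with only the compared groups in the fit. A trend of log2 CPM on exon length and GC content, a spline with 4 degrees of freedom, was removed from each library for lists of short genes. The steps were tested on simulated data with 200 changed genes per comparison, where a 2-fold change was recovered in 73.4% of genes for calorie restriction at 6 months, 65.2% at 12 months, 64.2% for methionine restriction, 59.1% for the receptor knockout and 73.8% for the Snell dwarf. False calls made up 4.37%, 3.01%, 7.09%, 9.32% and 11.5% of the calls in that order, above the nominal 5% in the last 3. Where a group had 1 to 3 counts in total, no fold is given. With 3 libraries per group, shares within single libraries were not reported with intervals, and all libraries were used in every main comparison.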

Results

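The 78 mouse liver libraries, in 26 groups of 3, covered 11 comparisons of an intervention with controls of the same strain, age and sex. Each value in parentheses is a log2 fold change ± SE from the edgeR fit, with n = 3 libraries per group. At 6 and 12 months it is the mean of the female and the male difference from controls of that sex. Unless a smaller number stands beside it, each gene named in a comparison with controls was shifted the same way in every treated library against the mean of its controls, in 6 of 6 libraries where both sexes were measured and in 3 of 3 elsewhere. Gene p-values use a spread pooled over the labelled replicates of all groups in the fit. Of 435 tests of fixed gene lists, 153 passed with camera's preset correlation between genes and 0 passed with a correlation estimated from the data, so the adjusted p of the second test stands beside each call as its estimated adjusted p. The deposited table does not state the strand of counting, and reads from near-identical paralogs (the Mup, Sult2a, Cyp2b, Cyp4a and Cyp3a41 families) were not resolved, so values of single members of these families are less certain than the others. Genes called the largest changes are those chosen by the naming rule.

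Marker genes of another tissue, chosen after the values were seen, had over 1000 counts in 9 libraries. The 10 kidney markers had 32760 counts in 17-alpha-estradiol male 2 and at most 35 elsewhere, and the 6 skeletal muscle markers 29604 in rapamycin male 3 of 12 months, 25469 in calorie-restricted female 2 and 3530 in calorie-restricted male 2 of 6 months and 6137 in Snell dwarf 1 (at most 263 elsewhere). The 4 adrenal markers had 42393 counts in rapamycin male 2 of 6 months and 4249 in calorie-restricted female 1 of 12 months, and the 8 pancreas markers 5483 in acarbose male 3 and 1123 in Protandim female 3 of 6 months. In a fit without these libraries, which leaves 2 in 9 groups, the genes changed at 6 months were 490 for acarbose in place of 913, 2551 for calorie restriction in place of 3873, 6 for rapamycin in place of 61, 4 for Protandim in place of 205 and 16 for 17-alpha-estradiol in place of 57. Between the sexes they were 6 for acarbose at 6 months in place of 56, 0 at 12 months in place of 1 and 0 for 17-alpha-estradiol in place of 8, and between the ages 83 for acarbose in place of 160. The bound of 1000 was set after a first fit that had kept Protandim female 3 and calorie-restricted female 1 of 12 months, in which Protandim changed 106 genes, so the fall to 4 depends on this bound.

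**Figure D1:**
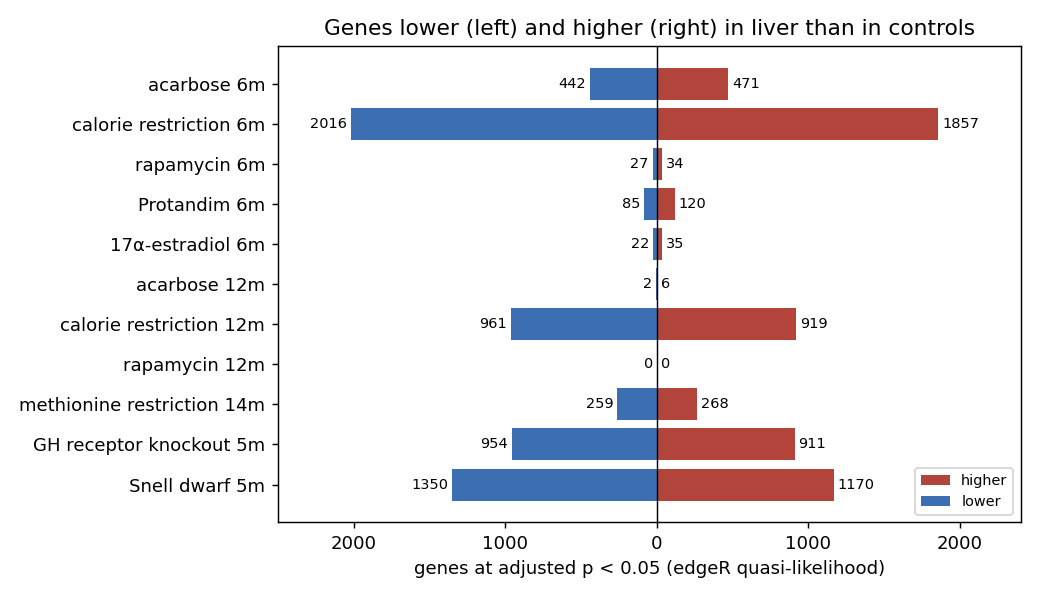
Genes at adjusted p under 0.05 in the edgeR quasi-likelihood fit for the 11 comparisons, with genes lower than in controls to the left and genes higher to the right, in numbers of genes. The bars ran from 0 genes for rapamycin at 12 months to 2016 lower and 1857 higher genes for calorie restriction at 6 months.

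Calorie restriction (40%, 2 months of treatment, animals 6 months old) lowered transcripts of endoplasmic reticulum protein folding and of the proteasome, and raised transcripts of ribosomal proteins, the respiratory chain and lipid synthesis. Of 20 measured members of the endoplasmic reticulum chaperone list, 17 fell and 0 rose, among them Calr (-1.36 ± 0.17), Hspa5 (-1.83 ± 0.24), Xbp1 (-0.69 ± 0.10) and Dnajb11 (-1.16 ± 0.17). Hspa5 (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547 on GRCm38) encodes BiP, the main chaperone of that compartment, and Xbp1 encodes a transcription factor of the unfolded protein response. Median log2 fold change over the list was -1.06 (camera adjusted p = 4.7e-11, estimated adjusted p = 0.557). Of 31 proteasome subunits, 25 fell and 0 rose, led by Psmd1 (-0.85 ± 0.07), Psmd14 (-0.93 ± 0.09), Psmd2 (-0.72 ± 0.07) and Psmc1 (-0.62 ± 0.08), with a list median of -0.43 (camera adjusted p = 1.67e-16, estimated adjusted p = 0.446). Ribosomal protein transcripts rose in 55 of 77 cases with 0 falling (median 0.35, camera adjusted p = 6.89e-16, estimated adjusted p = 0.625), for example Rps24 (0.52 ± 0.09) and Rps4x (0.46 ± 0.08), and 65 rose when adjusted over the list alone. Nuclear genes of the respiratory chain rose in 48 of 76 cases with 0 falling, for example Sdhb (0.60 ± 0.09) and Ndufa5 (0.48 ± 0.07) (median 0.30, camera adjusted p = 1.43e-15, estimated adjusted p = 0.626), and 62 rose when adjusted over the list alone.

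Among the largest increases were Thrsp (3.93 ± 0.45), Ppp1r3g (3.52 ± 0.57), Gstm3 (2.91 ± 0.45) and Cyp2b10 (2.81 ± 0.57). Thrsp (ENSMUSG00000035686, chromosome 7, 97412938 to 97417730) encodes a regulator of lipogenic enzymes. Most of the largest decreases were in major urinary protein genes, which encode pheromone carriers: Mup17 (-3.53 ± 0.48), Mup9 (-3.23 ± 0.52), Mup18 (-3.21 ± 0.95) and Mup14 (-3.12 ± 0.55). Lipogenesis genes rose in 11 of 19 cases and fell in 1, with Dgat2 (0.83 ± 0.12), Pklr (1.28 ± 0.20) and Acly (0.74 ± 0.12) next to Thrsp (camera adjusted p = 1.47e-05, estimated adjusted p = 0.351). Cholesterol synthesis genes rose in 8 of 22 cases and fell in 1, as in Pmvk (1.45 ± 0.21), Acat2 (0.93 ± 0.17) and Dhcr7 (0.97 ± 0.21) (camera adjusted p = 0.000133, estimated adjusted p = 0.767). Fatty acid oxidation genes fell in 13 of 30 cases and rose in 2, with Hadha (-0.46 ± 0.09) and Ehhadh (-1.22 ± 0.25) (camera adjusted p = 0.000629, estimated adjusted p = 0.755). Drug and steroid metabolism genes rose in 11 of 22 cases and fell in 1, including Abcb1a (2.43 ± 0.23), Por (1.24 ± 0.15) and Cyp2a5 (2.26 ± 0.35) (camera adjusted p = 1.05e-05, estimated adjusted p = 0.244). Clock genes changed in 12 of 18 cases, with Nr1d1 (-2.49 ± 0.26), Per2 (1.78 ± 0.26) and Cry1 (2.34 ± 0.19) among them. The labels give no hour of collection.

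In all, 3873 genes passed, 1857 up and 2016 down, of 14816 tested, and leaving out 1 library gave between 3033 and 3875. The effect differed between the sexes for 1 gene, Cyp2b9, a steroid hydroxylase expressed mainly in female liver, with a male minus female difference of 6.87 ± 0.77 (adjusted p = 3.08e-05). Its change was 6.59 ± 0.63 in males and -0.28 ± 0.47 in females. That count was 2 without control male 2 and 3 without calorie-restricted male 1, and DESeq2 gave 28.

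At 12 months, after 8 months of calorie restriction, many cytosolic and mitochondrial heat shock genes rose and many interferon response genes fell. Of 16 heat shock members, 12 rose and 0 fell, including Hspa4l (1.71 ± 0.19), Hspd1 (0.72 ± 0.10), Hsp90aa1 (2.00 ± 0.28) and Hsp90ab1 (1.10 ± 0.16) (median 1.0, camera adjusted p = 3.42e-10, estimated adjusted p = 0.417). Of 25 interferon response members, 12 fell and 0 rose, including Iigp1 (-1.10 ± 0.13), Xaf1 (-1.53 ± 0.30), Gbp7 (-0.88 ± 0.19) and Oas1a (-1.46 ± 0.32) (camera adjusted p = 4.42e-08, estimated adjusted p = 0.444). Large increases included Cyp2a4 (3.71 ± 1.04), Cyp4a14 (3.61 ± 1.13), Cyp39a1 (3.33 ± 0.52), Tsku (3.31 ± 0.52) and Tfrc (3.07 ± 0.43). The largest decreases were in Nr1d1 (-5.34 ± 0.50), Rgs16 (-3.00 ± 0.89), Fabp5 (-2.30 ± 0.54) and Gnat1 (-2.08 ± 0.33). Nr1d1 encodes the clock repressor REV-ERB alpha, and Cry1 (2.67 ± 0.20) and Per2 (1.99 ± 0.46) of the clock lists rose. Autophagy and lysosome genes fell in 6 of 26 cases and rose in 1, with Wipi1 (-1.33 ± 0.14), Ulk1 (-1.55 ± 0.21) and Gabarapl1 (-1.05 ± 0.16) (camera adjusted p = 0.0252, estimated adjusted p = 0.755). Citric acid cycle genes rose in 6 of 17 cases, including Idh2 (0.87 ± 0.14) and Mdh2 (0.60 ± 0.13) (camera adjusted p = 0.000619, estimated adjusted p = 0.444). In addition, 13 of 76 nuclear respiratory chain genes rose, including Cycs (0.70 ± 0.11) and Atp5b (0.34 ± 0.09) (camera adjusted p = 9.13e-12, estimated adjusted p = 0.755). Ribosomal protein transcripts rose in 7 of 77 cases, and in 0 when adjusted over the list alone (camera adjusted p = 5.71e-10, estimated adjusted p = 0.767). In total 1880 genes passed, 919 up and 961 down, of 13639 tested, and leaving out 1 library gave between 1311 and 1928. Between the sexes the effect differed for 0 genes in edgeR, where 453 had an unadjusted p under 0.05, and for 4 in DESeq2.

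The calorie restriction effect at 12 months differed from that at 6 months for 1938 genes, 1034 with a higher and 904 with a lower effect at 12 months, in a fit of both ages together. Age was joined there to the length of treatment. The endoplasmic reticulum chaperones shifted upward together: 17 of 20 members had a higher effect at 12 months and 0 a lower one, with a median difference of 1.35 (camera adjusted p = 1.17e-16, estimated adjusted p = 0.242). Hspa5 went from -1.83 ± 0.24 at 6 months to 0.70 ± 0.22 at 12 months, a difference of 2.52 ± 0.33 (adjusted p = 1.26e-06). At 12 months alone 5 of the 20 members rose and 0 fell (median 0.36, camera adjusted p = 0.00401, estimated adjusted p = 0.786). Proteasome subunits had a higher effect at 12 months in 18 of 31 cases (camera adjusted p = 4.79e-17, estimated adjusted p = 0.375), cytosolic and mitochondrial heat shock genes in 10 of 16 (camera adjusted p = 3.76e-07, estimated adjusted p = 0.385) and fatty acid oxidation genes in 13 of 30 (camera adjusted p = 4.39e-07, estimated adjusted p = 0.385). Lipogenesis genes had a lower effect at 12 months in 5 of 19 cases (camera adjusted p = 0.000841, estimated adjusted p = 0.424), and cholesterol synthesis genes in 5 of 22 (camera adjusted p = 0.000469, estimated adjusted p = 0.778). The largest positive differences were in Cyp4a14 (5.05 ± 1.06), Cyp4a31 (4.36 ± 1.18) and Cyp4a10 (3.87 ± 0.68), and the largest negative ones in Rgs16 (-4.67 ± 0.87), Dbp (-4.19 ± 1.24) and Thrsp (-3.22 ± 0.75). Across 13484 genes tested at both ages, which are not independent replicates, the log2 fold changes correlated with r = 0.277 (Spearman rho = 0.238, leave-one-library-out SE of r = 0.0722); r was 0.141 without the filter on low counts and 0.151 in DESeq2. Both ages called 278 genes up, against 120 by chance, 295 genes down, against 140, and 188 in opposite directions, against 260.

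**Figure D2:**
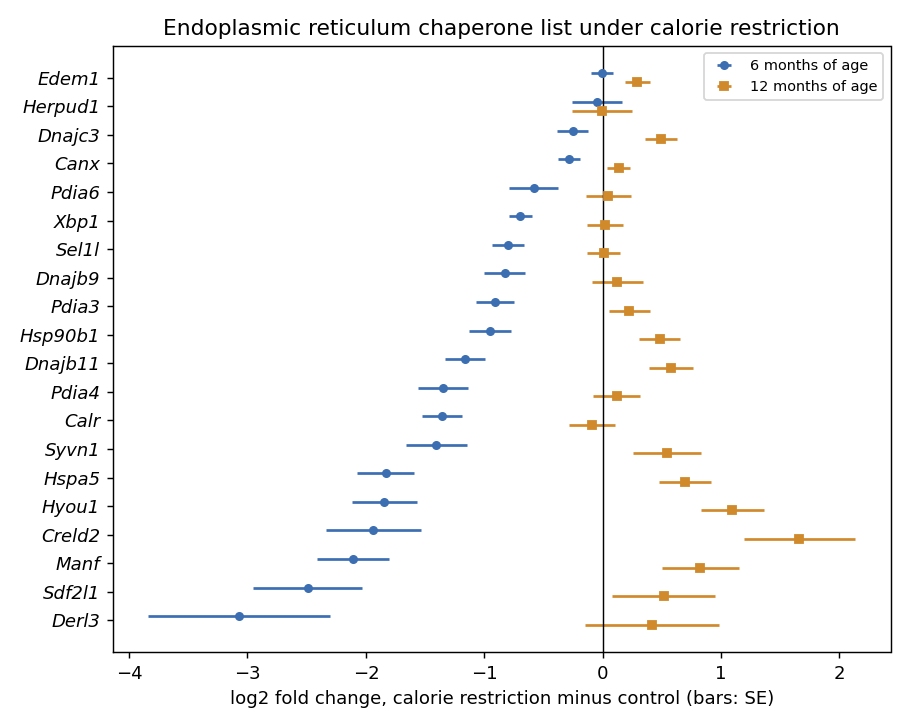
Log2 fold changes (calorie restriction minus control, mean of both sexes, bars SE) of the 20 measured members of the endoplasmic reticulum chaperone list at 6 months (circles) and 12 months (squares) of age. At 6 months 17 of the 20 fell, and at 12 months 5 rose.

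Acarbose (1000 ppm, 2 months of treatment, animals 6 months old), an inhibitor of intestinal carbohydrate digestion, raised glutathione transferase genes and lowered genes of methionine metabolism and glucose synthesis. Of 22 measured targets of the transcription factor NRF2, 11 rose and 0 fell, and 14 rose when adjusted over the list alone, with Gsta1 (3.90 ± 0.55), Gsta2 (1.71 ± 0.26) and Ugdh (0.91 ± 0.16) (median 0.47, camera adjusted p = 3.41e-11, estimated adjusted p = 0.244). The largest increases were in Gstm3 (2.90 ± 0.45), Cyp26a1 (2.42 ± 0.39), Meg3 (2.03 ± 0.51) and Osgin1 (1.81 ± 0.38). Cyp26a1 encodes a retinoic acid hydroxylase. The largest decreases were in Cyp8b1 (-2.42 ± 0.43), Cyp7a1 (-2.17 ± 0.56), Lamb3 (-1.92 ± 0.40) and Got1 (-1.68 ± 0.38). Cyp7a1 encodes the rate-limiting enzyme of bile acid synthesis and Cyp8b1 the sterol 12-alpha-hydroxylase. In the bile acid list 3 of 18 members rose and 3 fell (camera adjusted p = 0.463), and the transporter genes Abcb11 (0.82 ± 0.12) and Slc51b (3.40 ± 0.50) were among those that rose. Gluconeogenesis genes fell in 5 of 12 cases with 0 rising, as in Pcx (-0.40 ± 0.08, in 5 of 6 libraries) and Fbp1 (-0.64 ± 0.14) (camera adjusted p = 4.53e-06, estimated adjusted p = 0.417). Methionine and one-carbon genes fell in 4 of 18 cases and rose in 1, as in Mat1a (-0.96 ± 0.17), Mthfd1 (-0.41 ± 0.08) and Bhmt (-1.67 ± 0.34, in 4 of 6 libraries) (camera adjusted p = 3.02e-05, estimated adjusted p = 0.394). Fatty acid oxidation genes fell in 7 of 30 cases with 0 rising, as in Acsl1 (-0.72 ± 0.13) and Cpt1a (-0.81 ± 0.15) (camera adjusted p = 9.19e-08, estimated adjusted p = 0.566). The cell cycle list had 3 of 22 members up, Ccna2 (1.43 ± 0.37), Mki67 (1.3 ± 0.36) and Mcm7 (0.34 ± 0.10), and 8 when adjusted over the list alone (camera adjusted p = 9.84e-07, estimated adjusted p = 0.244).

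Acarbose at 6 months changed 913 genes, 471 up and 442 down. The 3 acarbose females lay apart from the other 6-month libraries on principal component 4, which held 5.88% of the variance, at -35.9, -54.2 and -57.7. The effect differed between the sexes for 56 genes, 24 with a higher and 32 with a lower effect in males. Bhmt, which encodes betaine homocysteine methyltransferase, changed by -3.29 ± 0.51 in females and -0.04 ± 0.47 in males, a difference of 3.25 ± 0.68 (adjusted p = 0.0375). Oat, the ornithine aminotransferase gene, changed by -1.60 ± 0.26 in females and 0.34 ± 0.25 in males, a difference of 1.94 ± 0.36. Higher effects in males were also found for Chrna2 (1.53 ± 0.31), Mat1a (1.51 ± 0.33) and Lhpp (1.42 ± 0.29), and lower ones for Nid1 (-1.88 ± 0.42), Ier5 (-1.83 ± 0.40) and Isyna1 (-1.56 ± 0.32). Within the sexes, edgeR called 1575 genes in females and 0 in males, where 1262 had an unadjusted p under 0.05 and DESeq2 called 20. Leaving out 1 library moved the count of 913 to 353 without acarbose female 3, 497 without acarbose female 2 and 507 without control male 1. It was 547 without acarbose male 3, 605 without acarbose male 1 and 2044 without acarbose female 1. It moved the count of 56 to 2 without control female 1, 3 without control male 3 and 6 without acarbose male 2 or acarbose male 3. It was 7 without acarbose female 3 or control female 3, 13 without control male 1 and 23 without control female 2. It was 34 without acarbose female 2 and 388 without acarbose female 1. With only the compared groups in the fit the counts were 240 and 3, and DESeq2 gave 315 genes that differed between the sexes.

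At 12 months, after 8 months of acarbose, 8 genes passed, 6 up and 2 down. The glutathione transferase genes Gsta2 (2.31 ± 0.37) and Gsta4 (0.91 ± 0.17) rose, as did Acmsd (1.27 ± 0.23), an enzyme gene of tryptophan breakdown, the mitochondrial isocitrate dehydrogenase gene Idh2 (0.79 ± 0.14), the lysosomal hexosaminidase gene Hexa (0.77 ± 0.13) and the bile acid transporter gene Slc51b (1.93 ± 0.29). The G protein gene Gna14 fell (-1.36 ± 0.23), as did Mycn (-2.66 ± 0.50, adjusted p = 0.0472), which lies outside the naming rule and was named after its values were seen. In the drug metabolism list 0 of 22 members passed over all genes, and 9 rose when adjusted over the list alone (median 0.38, camera adjusted p = 1.71e-12, estimated adjusted p = 0.149). Amino acid and urea cycle genes gave 0 of 25 over all genes and 10 up over the list alone (camera adjusted p = 1.72e-12, estimated adjusted p = 0.149), and interferon response genes 0 of 25 over all genes and 17 down over the list alone (median -0.58, camera adjusted p = 6.89e-16, estimated adjusted p = 0.244). The count of 8 became 0 without control female 1, 2 without acarbose female 3, acarbose male 1 or control male 2 and 3 without control male 1 or control male 3. It was 4 without acarbose male 3, 5 without control female 3 and 14 without control female 2. It was 22 without acarbose female 2. DESeq2 called 96 and 1 passed with only the compared groups in the fit. The effect differed between the sexes for 1 gene, Ifi202b, named after its values were seen, which had 0 counts in each of the 3 control males and 8, 38 and 14 counts in the 3 acarbose males. The calorie-restricted males of that age had 19, 16 and 29 and the rapamycin males 22, 16 and 19, so the control males stood apart from all treated males. DESeq2 called 3 genes. The count was 0 without acarbose female 1, acarbose female 3, acarbose male 2, control female 1 or any 1 control male.

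Between the ages, the acarbose effect differed for 160 genes, 86 with a higher and 74 with a lower effect at 12 months. Cyp7a1 had a higher effect at 12 months (3.69 ± 0.81), as did Cyp39a1 (3.27 ± 0.79), Upp2 (2.56 ± 0.58) and Bhmt (2.35 ± 0.43), and lower effects were found for Ly6a (-3.65 ± 0.89), Gstm3 (-2.65 ± 0.58) and Lhx6 (-1.65 ± 0.42). Methionine and one-carbon genes had a higher effect at 12 months in 6 of 18 cases, with a median difference of 0.56 (camera adjusted p = 3.36e-11, estimated adjusted p = 0.0364), and of the lists tested on differences between ages this 1 held its call with the estimated correlation. Across genes, which are not independent replicates, the log2 fold changes at the 2 ages correlated with r = 0.0494 (rho = 0.0976, SE 0.118). Leaving out 1 library moved the count of 160 to 66 without 12-month control female 1, 72 without 6-month acarbose female 3 and 74 without 12-month acarbose male 1. It was 94 without 6-month control male 2 or 12-month acarbose female 1, 95 without 6-month acarbose male 1 and 321 without 6-month acarbose female 1. It was 82 without the filter on low counts, 9 with only the compared groups in the fit and 330 in DESeq2.

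Rapamycin (42 ppm, 2 months, animals 6 months old), an inhibitor of the mTOR kinase, changed 61 genes, 34 up and 27 down, a count that moved with single libraries. Among the largest increases were mt-Tn (1.15 ± 0.23), mt-Nd3 (1.04 ± 0.24), Ifitm3 (0.78 ± 0.18) and Tmsb10 (0.77 ± 0.14). Among decreases, the largest were in Ntn4 (-1.42 ± 0.31), Lars2 (-1.23 ± 0.25), Ip6k2 (-0.75 ± 0.16) and Slc16a10 (-0.68 ± 0.15). Of 25 interferon response genes, 1 rose over all genes and 17 rose when adjusted over the list alone (median 0.79, camera adjusted p = 4.47e-13, estimated adjusted p = 0.417). Cholesterol synthesis genes gave 0 of 22 over all genes and 12 up over the list alone (median 0.64, camera adjusted p = 1.34e-12, estimated adjusted p = 0.557). The count of 61 became 0 without control female 1, control male 1, rapamycin female 2 or rapamycin female 3, 3 without rapamycin female 1 and 6 without rapamycin male 3. It was 8 without rapamycin male 2, 11 without rapamycin male 1 and 13 without control male 2. It was 14 without control female 2 and 219 without control male 3. It was 4 without the filter on low counts, 0 with only the compared groups in the fit, 300 in DESeq2, and 6 without rapamycin male 2 and calorie-restricted female 2. Of the 6-month libraries, these 2 were least correlated with their groups (r = 0.959 and 0.965 against a median of 0.978). The effect differed between the sexes for 0 genes in edgeR, with 738 at an unadjusted p under 0.05, for 2 in DESeq2, and for 1 without rapamycin female 1.

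At 12 months, after 8 months at the lower dose of 14 ppm, edgeR called 0 genes, with 665 at an unadjusted p under 0.05, and DESeq2 called 13. Interferon response genes pointed the other way from 6 months, with a median of -0.35 and 4 down when adjusted over the list alone (camera adjusted p = 6.48e-10, estimated adjusted p = 0.394). The difference between the ages had a median of -1.13 over that list (camera adjusted p = 2.41e-21, estimated adjusted p = 0.0624), with 0 of 25 members passing. T and NK cell markers had a median of -1.19 (camera adjusted p = 0.000339, estimated adjusted p = 0.385). Hepatocyte markers had 0.34 (camera adjusted p = 0.00277, estimated adjusted p = 0.385). Sinusoidal endothelial markers had 0.35 (camera adjusted p = 0.000298, estimated adjusted p = 0.554). The other cell lists were not called. Lists of other pathways were, such as cholesterol synthesis with -0.73 (camera adjusted p = 7.88e-10, estimated adjusted p = 0.385). At 12 months alone T and NK cell markers had a median of -1.13 (camera adjusted p = 2.26e-06, estimated adjusted p = 0.444). Within the sexes, named after their values were seen, edgeR called Slco1a1 (4.37 ± 0.66, adjusted p = 0.0418), an organic anion transporter gene expressed mainly in male liver, and Mgat2 (0.70 ± 0.12, adjusted p = 0.0453) in females, and Ifi202b in males, with 22, 16 and 19 counts against 0 in each control male. The female count became 0 without control female 1 or control female 2 and 1 without rapamycin female 1, rapamycin female 2 or rapamycin female 3, and the male count 0 without control male 1, control male 2, control male 3 or rapamycin male 3, 6 without rapamycin male 1 and 9 without rapamycin male 2; both were 0 without the 9 libraries. Sexes differed in the effect for 0 genes in edgeR, with 773 at an unadjusted p under 0.05, for 5 in DESeq2, and for 2 without rapamycin female 3. Dose, age and length of treatment changed together between the ages, and edgeR called 0 genes for the difference, with 1513 at an unadjusted p under 0.05, against 80 in DESeq2. Across genes the 2 ages gave r = -0.0610 (rho = -0.0411, SE 0.137), and r was 0.0771 without the filter on low counts and 0.149 in DESeq2. The count at 12 months was 1 without rapamycin female 3, and the count for the difference between ages ran from 0 to 36, highest without 12-month control female 3.

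Protandim (1200 ppm, 2 months, animals 6 months old), a mixture of plant extracts, changed 205 genes, 120 up and 85 down. The largest increases were in Cyp17a1 (2.32 ± 0.55), Trim24 (0.97 ± 0.25), Dexi (0.95 ± 0.21) and Selenow (0.90 ± 0.18). Decreases were largest in mt-Atp8 (-0.94 ± 0.16), Setdb2 (-0.92 ± 0.22), Enpp2 (-0.71 ± 0.18) and Emc1 (-0.61 ± 0.13). Ribosomal protein transcripts rose in 10 of 77 cases, for example Rpl23a (0.45 ± 0.09) and Rps21 (0.50 ± 0.11), and in 41 when adjusted over the list alone (median 0.27, camera adjusted p = 2.75e-20, estimated adjusted p = 0.566). Nuclear respiratory chain genes rose in 4 of 76 cases, for example Atp5e (0.54 ± 0.11) and Ndufa11 (0.52 ± 0.12) (camera adjusted p = 8.1e-13, estimated adjusted p = 0.706), while the mitochondrially encoded mt-Co2 (-0.81 ± 0.20) fell. Over the other genes, log2 fold change fell with exon length, with rho = -0.281 across genes. None of the 22 NRF2 targets passed, over all genes or over the list alone (camera adjusted p = 0.469). The count of 205 became 1 without control male 1, 2 without Protandim male 1 and 3 without Protandim female 2. It was 5 without control female 1, 14 without Protandim female 3 and 17 without control female 2. It was 56 without Protandim male 3, 75 without Protandim male 2 and 953 without Protandim female 1, 46 without the filter on low counts, 0 with only the compared groups in the fit and 684 in DESeq2. A difference between the sexes passed for 0 genes in edgeR, with 1689 at an unadjusted p under 0.05, and for 100 in DESeq2. Without 1 library that count ran from 0 to 255, highest without Protandim female 1.

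17-alpha-estradiol (14.4 ppm, 2 months, animals 6 months old), a stereoisomer of estradiol with weak estrogenic action, changed 57 genes, 35 up and 22 down. Apoc2 (ENSMUSG00000002992, chromosome 7, 19671579 to 19677941), the gene of the cofactor of lipoprotein lipase, rose by 1.99 ± 0.13 (adjusted p = 6.75e-11), and Mmd2 (2.91 ± 0.37) and the inositol synthesis gene Isyna1 (1.43 ± 0.16) rose with it. Further increases were in Osbpl3 (1.36 ± 0.26), Tnfrsf19 (1.23 ± 0.28) and Wsb1 (0.99 ± 0.22), and decreases in Rgs16 (-1.58 ± 0.35), Hes1 (-1.01 ± 0.21), Igfbp2 (-0.86 ± 0.20) and Slc25a47 (-0.69 ± 0.16). Fatty acid oxidation genes gave 0 of 30 over all genes and 14 down over the list alone (median -0.31, camera adjusted p = 3.16e-12, estimated adjusted p = 0.417), and endoplasmic reticulum chaperones 0 of 20 and 15 down (median -0.49, camera adjusted p = 2.16e-10, estimated adjusted p = 0.566). In females 425 genes passed, 219 up and 206 down, with Ciart (3.62 ± 0.99), Mup20 (2.98 ± 0.76) and Mmd2 (2.57 ± 0.50) the largest increases and Fgf21 (-2.61 ± 0.64), Apoa4 (-1.87 ± 0.52) and Acot2 (-1.58 ± 0.42) the largest decreases. In males 9 genes passed, all up: Apoc2 (2.46 ± 0.19), Isyna1 (1.65 ± 0.23), Galc (0.99 ± 0.19) and Spp1 (0.98 ± 0.19) by the rule, and Mmd2 (3.25 ± 0.53), Bnc2, Miox, Napsa and Dnase1, named after their values were seen. Bnc2 had 31, 95 and 19 counts in treated males 1, 2 and 3, Miox 4, 2873 and 5, Napsa 7, 748 and 7 and Dnase1 39, 1093 and 30, against 3, 3, 17 and 102 over the 3 controls in that order, so Miox, Napsa and Dnase1 were high in male 2, the library with kidney markers. Without it 3 genes passed, Apoc2, Isyna1 and Mmd2, and the adjusted p was 0.162 for Bnc2 and 1 for the other 5. The change was then 0.78 for Galc and Spp1, but fell from 5.4 to 0.56 for Napsa and from 3.5 to 0.29 for Dnase1. The difference between the sexes was tested separately and passed for 8 genes, 2 higher in males, Picalm (0.73 ± 0.13) and Paip1 (0.53 ± 0.10), and 6 lower, including Tk1 (-1.92 ± 0.35) and Plekhg6 (-1.71 ± 0.33).

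The 17-alpha-estradiol counts moved with the processing and with single libraries. The count of 57 was 12 without the filter on low counts, 26 with only the compared groups in the fit and 338 in DESeq2, and the female count 128, 108 and 825 in that order. The male count was 5 with a replicate block and 54 in DESeq2. The count that differed between the sexes was 0 without the filter, 3 with only the compared groups, 5 with RLE size factors and 118 in DESeq2. The count of 57 became 8 without treated male 2, 9 without control male 2 and 13 without control male 1. It was 14 without treated female 1, 17 without control female 1 and 20 without treated female 3. It was 23 without control female 3, 27 without treated female 2 and 191 without control male 3. The female count ran from 20 without control female 1 to 279 without control female 2. The male count became 2 without control male 1 or control male 2 and 3 without control male 3 or treated male 2. It was 79 without treated male 1 or treated male 3. The count that differed between the sexes became 0 without control male 3, any 1 treated female, treated male 2 or treated male 3. It was 1 without control female 1 or control female 3 and 2 without treated male 1. It was 5 without control female 2 and 44 without control male 2.

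Methionine restriction (0.12% against 0.86% methionine for 12 months, C57BL6/J males, 14 months old) changed 527 genes, 268 up and 259 down. In the integrated stress response list 8 of 23 members rose and 0 fell, with Aldh1l2 (4.59 ± 0.26), Asns (3.77 ± 0.32), Phgdh (5.21 ± 0.52) and Psat1 (4.25 ± 0.44) (median 0.81, camera adjusted p = 1.6e-06, estimated adjusted p = 0.557). Asns (ENSMUSG00000029752, chromosome 6, 7675169 to 7693254) encodes asparagine synthetase, and Phgdh and Psat1 enzymes of serine synthesis. NRF2 targets rose in 13 of 23 cases with 0 falling, as in Gsta2 (4.47 ± 0.18), Ephx1 (2.13 ± 0.12), Gsta4 (2.39 ± 0.16) and Gstm1 (1.65 ± 0.13) (camera adjusted p = 2.51e-14, estimated adjusted p = 0.394). Further large increases were in Cyp2a4 (6.54 ± 1.05), Cyp4a14 (4.23 ± 0.18) and Vil1 (4.19 ± 0.46). The largest decreases were in Mup15 (-8.04 ± 0.57), Mup17 (-6.82 ± 0.46), Mup7 (-6.66 ± 1.04) and Mup1 (-5.11 ± 1.06). Acute phase genes fell in 8 of 24 cases with 0 rising, as in Saa1 (-2.88 ± 0.23), Saa2 (-3.17 ± 0.37), Orm2 (-2.66 ± 0.32) and Lcn2 (-3.00 ± 0.37) (camera adjusted p = 6.09e-08, estimated adjusted p = 0.557). Textbook male-biased liver genes fell in 9 of 18 cases and rose in 1 (median -1.97, camera adjusted p = 1.42e-09, estimated adjusted p = 0.609). Mitochondrially encoded genes fell in 1 of 13 cases, mt-Nd2 (-1.01 ± 0.21), and in 12 over the list alone (camera adjusted p = 2.88e-06, estimated adjusted p = 0.741). Their share of counts was 3.56%, 5.31% and 5.94% in controls 1, 2 and 3 and between 3.11% and 3.31% in the restricted animals.

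Methionine restriction control 1 lay apart on principal component 2 at -42.6. Leaving out 1 library gave 98 without restricted 2, 157 without control 3 and 165 without restricted 1. It was 186 without control 2, 308 without restricted 3 and 1728 without control 1, and DESeq2 called 1092.

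In the growth hormone receptor knockout (males, 5 months old) the targeted gene itself was lower, as the label states: Ghr (ENSMUSG00000055737, chromosome 15, 3317760 to 3583492) fell by 2.93 ± 0.20. Transcripts that growth hormone maintains in liver fell with it: Igf1 (-6.05 ± 0.18, adjusted p = 2.37e-07), Igfals (-5.05 ± 0.26) and Socs2 (-3.99 ± 0.86), which encode insulin-like growth factor 1, its carrier subunit and a feedback inhibitor. Textbook male-biased liver genes fell in 17 of 19 cases with 0 rising, as in Slco1a1 (-8.74 ± 0.32), Susd4 (-5.41 ± 0.23), C6 (-4.63 ± 0.26) and Ugt2b1 (-1.89 ± 0.14) (median -5.41, camera adjusted p = 2.09e-21, estimated adjusted p = 0.149). The filter kept 16 textbook female-biased genes in this set, against 25 in the joint fit of both ages. Of the 16, 10 rose with 0 falling, as in Slc22a27 (5.67 ± 0.22), Cyp17a1 (5.63 ± 0.31) and Atp6v0d2 (3.38 ± 0.38) (camera adjusted p = 1.05e-10, estimated adjusted p = 0.244). The sulfotransferase genes Sult2a1, Sult2a3 and Sult2a5 rose from 2, 2 and 3 counts over the 3 controls to 40962, 13391 and 11203 counts over the 3 knockouts, so no fold is given for them. Other large increases were in Sult2a2 (11.55 ± 0.84), Sult1e1 (9.40 ± 0.39) and Cyp2b13 (8.96 ± 1.21). Sult1e1 encodes estrogen sulfotransferase. The largest decreases were in Mup12 (-11.25 ± 0.76), Hsd3b5 (-10.76 ± 0.58), Mup7 (-9.65 ± 0.79) and Wfdc21 (-8.88 ± 0.30). Nuclear respiratory chain genes rose in 67 of 76 cases with 0 falling, as in Ndufa5 (0.91 ± 0.12) and Atp5h (0.77 ± 0.12) (median 0.58, camera adjusted p = 1.13e-23, estimated adjusted p = 0.583). Endoplasmic reticulum chaperones fell in 14 of 20 cases with 0 rising, as in Xbp1 (-0.92 ± 0.11) and Hyou1 (-1.19 ± 0.17) (camera adjusted p = 1.12e-07, estimated adjusted p = 0.557). In all 1865 genes passed, 911 up and 954 down, and leaving out 1 library moved the count to 1073 without control 2, 1089 without knockout 2 and 1157 without knockout 1. It was 1201 without control 1.

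Snell dwarf males (5 months old), which carry a mutation of the pituitary factor Pou1f1 and lack growth hormone, prolactin and thyrotropin, shared the low Igf1 (-4.89 ± 0.33), Igfals (-4.88 ± 0.42) and Socs2 (-3.32 ± 0.41), while Ghr fell by 0.60 ± 0.13. Male-biased genes fell in 18 of 19 cases, as in Hsd3b5 (-9.73 ± 0.20), C4a (-6.26 ± 0.28) and C6 (-4.58 ± 0.27) (median -4.82, camera adjusted p = 1.02e-17, estimated adjusted p = 0.351). Of the 16 female-biased genes kept by the filter, 11 rose and 1 fell, as in Fmo2 (2.98 ± 0.13), Cyp2a4 (6.66 ± 0.44) and Cyp2b13 (10.47 ± 0.66) (camera adjusted p = 4.58e-09, estimated adjusted p = 0.244). Other large increases were in Cyp2a22 (8.62 ± 0.27), Igfbp1 (7.69 ± 0.76), Mt2 (7.17 ± 1.12) and Mt1 (6.13 ± 0.78). The 8 largest decreases were all in Mup genes, from Mup12 (-11.66 ± 0.36) to Mup14 (-10.86 ± 0.25). Lipogenesis genes, several of them targets of thyroid hormone, fell in 10 of 19 cases with 0 rising, as in Me1 (-2.72 ± 0.14), Acacb (-2.87 ± 0.24) and Thrsp (-3.86 ± 0.47) (camera adjusted p = 5.62e-06, estimated adjusted p = 0.557). Endoplasmic reticulum chaperones fell in 14 of 20 cases with 0 rising, as in Hyou1 (-1.12 ± 0.10), Creld2 (-1.28 ± 0.12) and Sdf2l1 (-2.40 ± 0.26) (camera adjusted p = 1.71e-08, estimated adjusted p = 0.626). Drug metabolism genes rose in 13 of 22 cases and fell in 2, as in Cyp2c38 (4.73 ± 0.25) and Cyp2a5 (2.82 ± 0.23) (camera adjusted p = 5.16e-06, estimated adjusted p = 0.244). Ribosomal protein transcripts rose in 20 of 77 cases (camera adjusted p = 6.98e-09, estimated adjusted p = 0.758) and nuclear respiratory chain genes in 30 of 76 (camera adjusted p = 4.25e-10, estimated adjusted p = 0.767), both with 0 falling. Here 2520 genes passed, 1170 up and 1350 down, and leaving out 1 library moved the count to 1263 without control 1 and 1406 without control 2.

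The 2 dwarf models shared 448 genes up, against 80.1 by chance, and 557 genes down, against 101, while 9 went in opposite directions, against 180. Across 12234 genes, which are not independent replicates, their log2 fold changes correlated with r = 0.761 (rho = 0.619, SE 0.0257), and r was 0.432 without the filter on low counts and 0.473 in DESeq2. Calorie restriction at 6 months shared 348 genes up, against 124 by chance, and 346 down, against 147, with the receptor knockout, and 383 up, against 159, and 416 down, against 209, with the Snell dwarf. Methionine restriction shared 76 genes up, against 23.3, and 107 down, against 25.7, with the Snell dwarf, and 41 up, against 17.8, and 67 down, against 17.8, with the receptor knockout, where 58 went in opposite directions, against 35.7, and r was 0.253 and rho -0.0112 across genes. Acarbose at 6 months shared 57 genes up, against 8.92, and 20 down, against 8.08, with methionine restriction, and with the receptor knockout 119 genes went in opposite directions, against 64.5.

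In control livers at 6 months females were higher in Sult3a1 (10.32 ± 0.84), Cyp3a41a (9.86 ± 0.55) and Xist (9.29 ± 0.58) and lower in Cyp4a12a (-8.90 ± 0.65), Hsd3b5 (-8.58 ± 0.96) and Mup7 (-7.51 ± 0.94). Xist, the RNA of X inactivation, served as a check of the sex labels. At 12 months females were higher in A1bg (12.21 ± 1.52), Sult3a1 (11.15 ± 1.15) and Sult2a1 (10.54 ± 1.13) and lower in Cyp4a12a (-12.45 ± 0.74), Hsd3b5 (-9.44 ± 1.02) and Mup12 (-8.39 ± 1.73), and Cyp3a41a had 15215 counts over the 3 females and 2 over the 3 males. In all 738 genes differed at 6 months, 294 higher and 444 lower in females, and 393 at 12 months, 203 higher and 190 lower. The 6-month count was 354 without control female 1, 375 without control male 3 and 489 without control male 1, the 12-month count 184 without control male 2, 231 without control female 1 and 253 without control male 3. It was 261 without control female 2, and with only the controls in the fit the 6-month count was 312.

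Genes with an at least 2-fold sex difference in controls were followed in the male livers of each intervention. The lists came from the control samples of 12 months for the 6-month comparisons and from those of 6 months for the others, so that no library served both steps. They held 84 female-biased and 95 male-biased genes in common between the ages. In receptor knockout males the female-biased genes had a median of 1.24 (camera adjusted p = 2.54e-24, estimated adjusted p = 0.0458), with 60 of 135 up and 2 down, and the male-biased genes one of -1.25 (camera adjusted p = 1.1e-25, estimated adjusted p = 0.0108), with 93 of 183 down and 4 up. In Snell males the medians were 1.37 (camera adjusted p = 6.16e-20, estimated adjusted p = 0.0326) and -1.39 (camera adjusted p = 9.06e-22, estimated adjusted p = 0.0183), with 80 of 135 female-biased genes up and 98 of 183 male-biased genes down. Calorie restriction moved males the same way at both ages. At 6 months the medians were 0.39 (camera adjusted p = 5.43e-07, estimated adjusted p = 0.062) and -0.49 (camera adjusted p = 3e-08, estimated adjusted p = 0.0336), with 23 of 169 female-biased genes up and 25 of 141 male-biased genes down. At 12 months they were 0.36 (camera adjusted p = 8.59e-06, estimated adjusted p = 0.062) and -0.31 (camera adjusted p = 4.14e-05, estimated adjusted p = 0.0336), with 17 of 164 up and 15 of 201 down. Acarbose at 12 months gave 0.29 (camera adjusted p = 0.000306, estimated adjusted p = 0.122) and -0.19 (camera adjusted p = 0.00411, estimated adjusted p = 0.111), and methionine restriction 0.18 (camera adjusted p = 0.0449, estimated adjusted p = 0.631) and -0.32 (camera adjusted p = 0.000339, estimated adjusted p = 0.514). For rapamycin the male-biased genes had a median of -0.14 (camera adjusted p = 0.0122, estimated adjusted p = 0.323) at 6 months and 0.10 (camera adjusted p = 0.0122, estimated adjusted p = 0.151) at 12 months. Calls were absent at the preset correlation for both lists under acarbose at 6 months, Protandim and 17-alpha-estradiol.

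**Figure D3:**
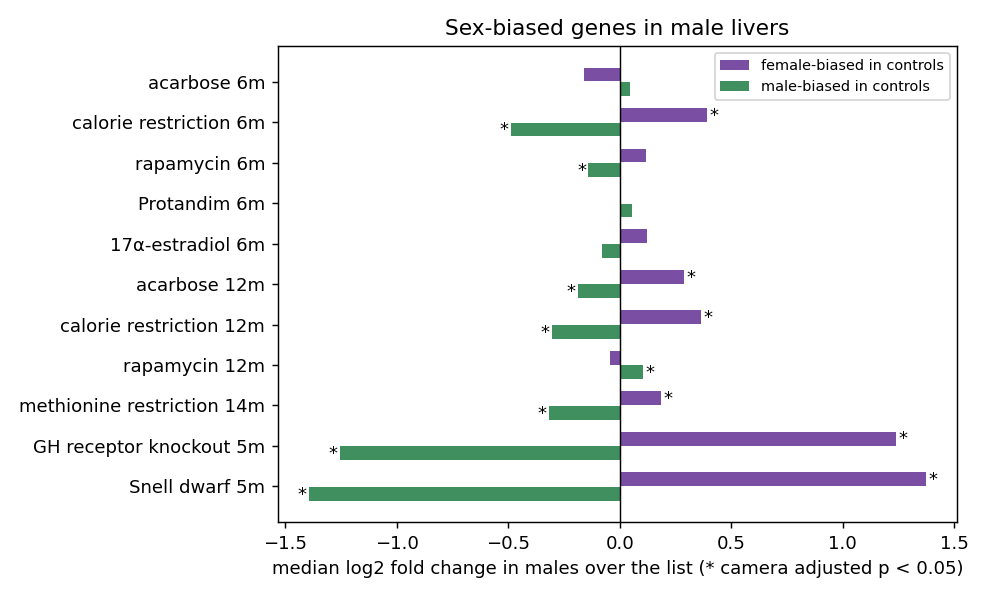
Median log2 fold change in males over the genes that were female-biased (purple) or male-biased (green) in controls, for the 11 comparisons, with asterisks at camera adjusted p under 0.05 with the preset correlation. In both dwarf models the female-biased median was 1.24 and 1.37, and the male-biased median -1.25 and -1.39.

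**Figure D4:**
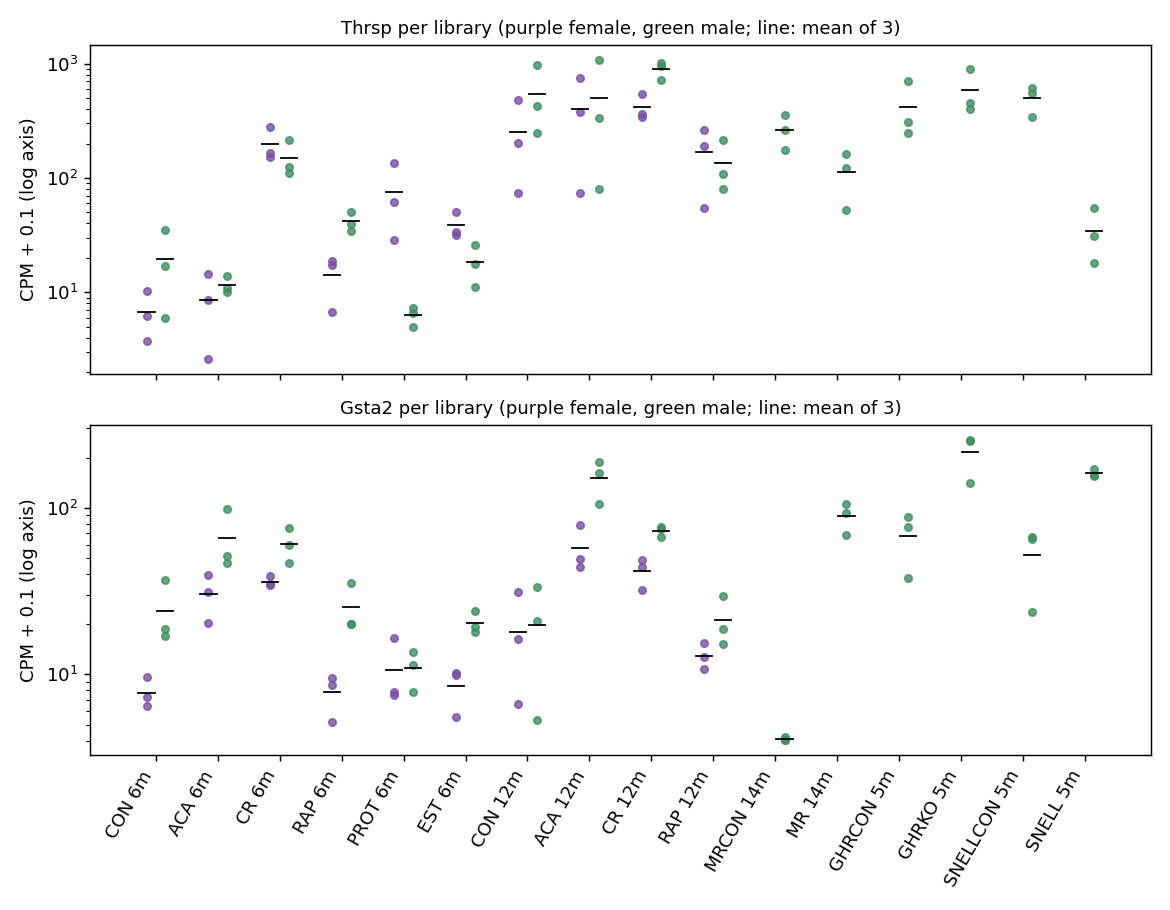
Depth-scaled counts (CPM), plus 0.1 on a log axis, of Thrsp (upper panel) and Gsta2 (lower panel) in every library, females in purple and males in green, with a line at the mean of each group of 3. Thrsp in males ran from 5.92 to 35.3 in the 6-month controls and from 110 to 216 in the calorie-restricted males of that age. In the males of 12 months it ran from 248 to 964 in controls and from 726 to 1021 under calorie restriction.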

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

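The tests of clock genes, of scaling and of other splits of the samples were chosen only after the results were seen, while those of gene length and GC content, of the spread among males and of single libraries were written beforehand. All 6 results here were listed because a test of the difference itself found effects of an intervention that differed between the sexes or between the ages. Effects differed between the sexes for 56 genes under acarbose at 6 months, for 1 gene under calorie restriction at 6 months, for 8 genes under 17-alpha-estradiol and for 1 gene under acarbose at 12 months. They differed between 12 and 6 months for 160 genes under acarbose and for 1938 genes under calorie restriction. Without 1 library the counts for acarbose ran from 2 to 388 between the sexes at 6 months and 66 to 321 between the ages. The highest for 17-alpha-estradiol was 44, without control male 2.

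With only the compared groups in the fit, other splits of the same libraries were set against the real one. For the difference between the ages under calorie restriction the real split called 1724 genes and the highest other split 591. The real one alone, 1 of 40 splits, called as many, which argues against chance. That is the smallest share these splits can give, and the tests were not adjusted together. For 17-alpha-estradiol between the sexes the values were 3 and 1, and 1 of 40 splits called as many. With a margin of 2 genes in such an unadjusted test, chance stays open. The count of 8 became 0 without the 9 libraries with markers of another tissue, without the filter on low counts, and without any 1 of 6 libraries, among them treated male 2 with the kidney markers, so RNA of kidney stays open. For acarbose at 12 months between the sexes the real split called 0 genes and the highest other 2, and with 0 real calls 40 of 40 splits call as many whatever the data, so the test says nothing about chance. Chance cannot be excluded by splits for the others. For acarbose at 6 months between the sexes the real split called 3 genes and the highest other 62, with 4 of 40 as large. For calorie restriction at 6 months between the sexes both values were 1, with 5 of 40 as large, and since such a count does not weigh the size of the change, the smallest adjusted p over all genes was also compared. It was 0.00682 in the real split, for Cyp2b9, and as low in 5 of 40, down to 9.63e-06 for Pttg1 in 1 split. The other 3 called Cyp2b9 and kept or exchanged all 3 restricted males together, so they carry the same difference. In the fit of all groups Cyp2b9 had a difference of 6.87 ± 0.77 (adjusted p = 3.08e-05). For acarbose between the ages the counts were 9 and 74, with 4 of 40 as large. The split that called 62 genes kept the 3 acarbose females and 2 of the 3 acarbose males under their own labels. The split that called 74 kept the 3 acarbose females and 2 of the 3 acarbose males of 6 months, with 2 females and 1 male of 12 months. Other splits that kept these females called 14, 12 and 1 genes between the sexes and 22 and 0 between the ages, and 1 that did not keep them called 9 between the ages. High counts of other splits point to a structure of the samples, which was not tested.

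The first pattern weighed was the calorie restriction effect on endoplasmic reticulum chaperones, with a median difference of 1.35 between 12 and 6 months over 20 members, 17 of them higher at 12 months. Scaling stays open, since RLE size factors, with a median of 1.36, moved the genes by a median of only 0.00901 and could not test it. Single libraries are argued against, since the median ran from 1.2, without control female 3 of 6 months, to 1.5 when each library was left out. Collection at another clock phase stays open, since 3 of 18 clock genes differed between the ages, against 2.30 by chance (Fisher's exact test, one-sided p = 0.410), and phase, time since the last meal and age cannot be told apart without collection hours. Calorie restriction changed 12 of 18 clock genes at 6 months, against 4.71 by chance (exact p = 0.000361), and 5 of 18 at 12 months, against 2.48 (exact p = 0.0908). The test treats the 18 genes as independent. An effect of age or of the length of restriction itself stays open and was not tested.

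The second pattern was that acarbose at 6 months called 1575 genes in females and 0 in males, where edgeR had 1262 at an unadjusted p under 0.05 and DESeq2 called 20. A larger spread among males is argued against, since the median within-group SD of log2 CPM in males was 0.830 of that in females. Of the 1575 genes, 1081 (68.6%) had the same sign in males, against 54.4% of the genes not called, with a median male change of 0.10 in the female direction beside a median of 0.71 in females. A clock phase particular to females stays open, with 1 of 18 clock genes called against 1.91 by chance (Fisher's exact test, one-sided p = 0.868), because the 18 genes are few; something shared by the 3 acarbose females, such as cage or time of feeding, was not recorded. A sex difference in the response to acarbose may exist, but the test of the difference passed for 56 genes in the fit of all groups and for 3 with only the compared groups, and the female count ran from 521 without acarbose female 3 to 2484 without acarbose female 1.

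The third pattern was that lists of short genes, ribosomal proteins and the nuclear respiratory chain, were called up at the preset correlation in 10 and 8 of 11 comparisons (the respiratory chain down in 1), with 0 calls at the estimated correlation. Comparisons at 1 age share their controls, so they are not independent, and the ribosomal difference passed 2 SE before correction only in calorie restriction at 6 months, Protandim and the Snell dwarf (0.314 ± 0.0868). After removing each library's trend on exon length and GC content, the list difference went from 0.340 ± 0.0983 to 0.296 ± 0.0924 for ribosomal proteins and from 0.290 ± 0.0843 to 0.262 ± 0.0744 for the respiratory chain under calorie restriction at 6 months, and from 0.585 ± 0.0811 to 0.465 ± 0.0479 for the respiratory chain in the receptor knockout, so such a trend is argued against as the whole cause of these 3. For ribosomal proteins under Protandim it went from 0.241 ± 0.086 to 0.160 ± 0.0928, within 2 SE of 0, and the trend stays open there because log2 fold change fell with exon length over the other genes (rho = -0.281 across genes). For rapamycin at 6 months the ribosomal list went from 0.106 to 0.0268, and for the receptor knockout from 0.137 to 0.00609, while corrected values above 2 SE were kept in the Snell dwarf (0.295 ± 0.0536) and reached in acarbose at 12 months (0.181 ± 0.0856, before 0.186 ± 0.129) and calorie restriction at 12 months (0.332 ± 0.144, before 0.348 ± 0.196). RNA quality was not recorded, and a higher synthesis of these messages under calorie restriction may be the biological alternative, which was not tested.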

How the results depend on the processing

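The fits without 2 libraries at 6 months and without 9 or 7 libraries with markers of another tissue were chosen after seeing the data, and the other alternatives were fixed earlier. No fold change of a named gene changed sign under an alternative, except Des under calorie restriction at 6 months without the 9 libraries (-0.0403). In that fit the named genes that held were 50 of 71 for acarbose, 110 of 128 for calorie restriction, 2 of 20 for rapamycin, 1 of 27 for Protandim and 4 of 16 for 17-alpha-estradiol at 6 months (4 of 10 in females, 2 of 4 in males), 7 of 7 for acarbose and 95 of 112 for calorie restriction at 12 months and 120 of 129 for the Snell dwarf. Between the sexes they were 1 of 10 for acarbose at 6 months, 1 of 1 for calorie restriction at 6 months, 0 of 6 for 17-alpha-estradiol and 10 of 10 in the controls of each age, and between the ages 4 of 10 for acarbose and 8 of 10 for calorie restriction. Signs changed for r across genes under rapamycin, from -0.0610 to the values below, and for medians of sex-biased lists in males that had not passed. Of the lists that had passed, 2 had medians that changed sign with 1 library left out: fatty acid oxidation under methionine restriction (-0.00615 to 0.206, lowest without restricted male 3) and ribosomal proteins in the receptor knockout (-0.00552 to 0.249, lowest without knockout male 1). Of 46 counts and correlations, 44 stayed within their range with RLE size factors, 25 without the filter on low counts, 37 with a replicate block and 13 in DESeq2, as did 18 of 39 with only the compared groups in the fit and 411 of 600 values with 1 library left out. Of 153 list calls, 151 held with RLE size factors, 152 without the filter, 150 with the block and 151 in DESeq2, while 0 held with the estimated correlation. Of 759 values of named genes, 753 held with RLE size factors, 618 without the filter, 693 with the block and 754 in DESeq2, as did 289 of 452 with only the compared groups and 5639 of 7302 with 1 library left out. DESeq2 raised and the fit of the compared groups lowered most counts that moved. The cause was not tested. Small effects were found less often: on simulated data a 1.5-fold change was recovered in 49.3% of genes for calorie restriction at 6 months and in 7.69% for the Snell dwarf. The replicate numbers did not pair the samples, so the block was not used in the reported values.

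Without the filter on low counts, the genes changed were 558 for acarbose at 6 months, 4 for rapamycin at 6 months, 46 for Protandim, 12 for 17-alpha-estradiol, 128 for 17-alpha-estradiol in females and 1 for rapamycin at 12 months. Counts between the sexes were 15 for acarbose at 6 months, 0 for 17-alpha-estradiol and 1 for calorie restriction at 12 months. Between the ages, counts were 82 for acarbose. R across genes was 0.141 for calorie restriction, 0.0771 for rapamycin and 0.432 for the dwarf models. The male-biased median in males was 0.10 for rapamycin at 12 months.

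With only the compared groups in the fit, the genes changed were 240 for acarbose at 6 months, 0 for rapamycin at 6 months, 0 for Protandim, 26 for 17-alpha-estradiol, 108 for 17-alpha-estradiol in females and 1 for acarbose at 12 months. Counts between the sexes were 3 for acarbose at 6 months, 3 for 17-alpha-estradiol and 0 for acarbose at 12 months. The sex difference in controls was 312 at 6 months. Between the ages, counts were 9 for acarbose and 1 for rapamycin. The female-biased median in males was 0.15 for 17-alpha-estradiol.

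In DESeq2, the genes changed were 300 for rapamycin at 6 months, 684 for Protandim, 338 for 17-alpha-estradiol, 825 for 17-alpha-estradiol in females, 54 for 17-alpha-estradiol in males, 96 for acarbose at 12 months, 13 for rapamycin at 12 months and 1092 for methionine restriction. Counts between the sexes were 315 for acarbose at 6 months, 28 for calorie restriction at 6 months, 2 for rapamycin at 6 months, 100 for Protandim, 118 for 17-alpha-estradiol, 3 for acarbose at 12 months, 4 for calorie restriction at 12 months and 5 for rapamycin at 12 months. The sex difference in controls was 613 at 12 months. Between the ages, counts were 330 for acarbose and 80 for rapamycin. R across genes was 0.151 for calorie restriction, 0.149 for rapamycin and 0.473 for the dwarf models. The female-biased median in males was 0.031 for methionine restriction.

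With a replicate block, the genes changed were 346 for Protandim, 5 for 17-alpha-estradiol in males and 5 for acarbose at 12 months. Counts between the sexes were 3 for Protandim and 0 for acarbose at 12 months. With RLE size factors, counts between the sexes were 5 for 17-alpha-estradiol. Without rapamycin male 2 and calorie-restricted female 2 of 6 months, the genes changed were 6 for rapamycin at 6 months. Without the 9 libraries, the genes changed were 490 for acarbose at 6 months, 2551 for calorie restriction at 6 months, 6 for rapamycin at 6 months, 4 for Protandim, 16 for 17-alpha-estradiol and 3 for 17-alpha-estradiol in males. Counts between the sexes were 6 for acarbose at 6 months, 0 for 17-alpha-estradiol and 0 for acarbose at 12 months. Between the ages, counts were 83 for acarbose. Without the 7 found first, the genes changed were 503 for acarbose at 6 months, 2513 for calorie restriction at 6 months, 4 for rapamycin at 6 months, 106 for Protandim, 9 for 17-alpha-estradiol, 266 for 17-alpha-estradiol in females and 3 for 17-alpha-estradiol in males. Those between the sexes were 18 for acarbose at 6 months and 0 for 17-alpha-estradiol. Between the ages, counts were 81 for acarbose. With textbook lists, the female-biased median in males was 0.0705 for acarbose at 6 months, -0.31 for rapamycin at 6 months, -0.50 for 17-alpha-estradiol and 0.37 for rapamycin at 12 months. The male-biased median in males was 0.16 for Protandim. The 4 female-biased medians had the opposite sign with the lists from controls.

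With an estimated correlation, which leaves medians as they are, 8 tests of sex-biased lists did not pass. For these the female-biased median in males was 0.39 for calorie restriction at 6 months, 0.29 for acarbose at 12 months, 0.36 for calorie restriction at 12 months and 0.18 for methionine restriction. The male-biased median in males was -0.14 for rapamycin at 6 months, -0.19 for acarbose at 12 months, 0.10 for rapamycin at 12 months and -0.32 for methionine restriction. With it 6 of the tests of sex-biased genes in males passed, against 14 with the preset correlation, and 0 of 435 tests of gene lists, against 153.

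When 1 library was left out, values moved as follows. The genes changed ran from 353 to 2044 for acarbose at 6 months, 0 to 219 for rapamycin at 6 months, 1 to 953 for Protandim, 8 to 191 for 17-alpha-estradiol, 20 to 279 for 17-alpha-estradiol in females, 2 to 79 for 17-alpha-estradiol in males, 0 to 22 for acarbose at 12 months, 0 to 1 for rapamycin at 12 months, 98 to 1728 for methionine restriction, 1073 to 1700 for the receptor knockout and 1263 to 2487 for the Snell dwarf. Counts between the sexes ran from 2 to 388 for acarbose at 6 months, 1 to 3 for calorie restriction at 6 months, 0 to 1 for rapamycin at 6 months, 0 to 255 for Protandim, 0 to 44 for 17-alpha-estradiol, 0 to 1 for acarbose at 12 months and 0 to 2 for rapamycin at 12 months. The sex difference in controls ran from 354 to 706 at 6 months and 184 to 280 at 12 months. Between the ages, counts ran from 66 to 321 for acarbose and 0 to 36 for rapamycin. R across genes ran from 0.733 to 0.763 for the dwarf models. The female-biased median in males ran from -0.31 to -0.0113 for acarbose at 6 months, -0.0114 to 0.25 for rapamycin at 6 months, 0.0407 to 0.18 for 17-alpha-estradiol, 0.0695 to 0.33 for acarbose at 12 months, -0.15 to 0 for rapamycin at 12 months and 0.0273 to 0.27 for methionine restriction. The male-biased median in males ran from -0.0153 to 0.11 for acarbose at 6 months, -0.25 to -0.0341 for rapamycin at 6 months, 0.00156 to 0.0779 for Protandim, -0.31 to -0.13 for acarbose at 12 months and 0.0676 to 0.13 for rapamycin at 12 months.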

Other observations

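The split tests here were chosen after the results were seen. Each pair gives the counts of the real and of the highest other split, with only the compared groups in the fit.

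Unadjusted splits argue against chance for 4 results. Counts were 240 and 18 for acarbose at 6 months, 3307 and 461 for calorie restriction at 6 months, 26 and 10 for 17-alpha-estradiol and 1753 and 4 for calorie restriction at 12 months, each with 1 of 40 as large, the smallest share. Chance stays open for acarbose at 12 months, with 1 and 8 (5 of 40 as large, and a smallest adjusted p as low in 4 of 40). For the rapamycin effect between the ages the values were 1 and 0 (1 of 40 as large), but edgeR called 0 genes in the fit of all groups, where 1513 had an unadjusted p under 0.05 and DESeq2 called 80, so there was no call for chance to explain.

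Where the real split called 0 genes, all 40 splits must call as many, so these tests say nothing about chance. The counts for changed genes were 0 and 4 for rapamycin at 6 months, 0 and 12 for Protandim and 0 and 142 for rapamycin at 12 months. For differences between the sexes they were 0 and 4 for rapamycin at 6 months, 0 and 32 for Protandim, 0 and 221 for calorie restriction at 12 months and 0 and 6 for rapamycin at 12 months. The split that called 221 genes kept 2 of the 3 restricted females under their own labels and exchanged the labels of all males, so that an effect shared by the sexes enters as a difference. The split that called 142 kept 2 of the 3 treated animals of each sex, and that with 32 kept 1 of 3. These may come from sample structure beyond the groups or from clustered false calls, which was not tested.

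With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The counts were 108 and 3 for 17-alpha-estradiol in females and 9 and 7 in males. For the sexes in controls they were 312 and 5 at 6 months and 265 and 3 at 12 months. They were 527 and 0 for methionine restriction, 1865 and 1 for the receptor knockout and 2520 and 1 for the Snell dwarf.

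Clock genes passed more often than other genes in females under calorie restriction at 6 months: 13 of 18, against 3.07 by chance (Fisher's exact test, one-sided p = 3.6e-07). The same was found in females under calorie restriction at 12 months, with 5 of 18, against 0.85 by chance (exact p = 0.00118), under 17-alpha-estradiol, with 5 of 18, against 0.516 by chance (exact p = 0.000119), and under Protandim, with 5 of 18, against 0.963 by chance (exact p = 0.00207). In males under calorie restriction they were 4 of 18, against 1.41 by chance (exact p = 0.0475) at 6 months and 3 of 18, against 0.557 by chance (exact p = 0.017) at 12 months. These 6 groups had the smallest p of the within-sex tests, the p-values are unadjusted, the tests were chosen after the results were seen, and the labels give no hour of collection. The gene counts in these groups moved when 1 library was left out. The 2523 for females under calorie restriction at 6 months became 1389 without calorie-restricted female 2 and 1567 without control female 1, and the 644 at 12 months 186 without calorie-restricted female 2, 235 without control female 1 and 269 without control female 2. It was 352 without calorie-restricted female 1. The 793 under Protandim ran from 0 without Protandim female 2 to 2127 without Protandim female 1 (0 without the 9 libraries and 634 without the 7 found first), the 425 under 17-alpha-estradiol from 20 to 279, and those of the males from 553 to 1258 at 6 months, against 1162, and from 139 to 243 at 12 months, against 422. Clock genes were not counted again in those fits.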
